A study of Mus musculus with 8 samples.

How the data were processed

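Messenger RNA levels were measured by bulk RNA-seq of mouse retina at embryonic day 14.5 (E14.5), in 4 libraries labelled wild type (WT) and 4 labelled knockout (KO) of a large enhancer of Atoh7. The labels name the deleted element in more than 1 way, and its coordinates are not given in the sources used here. The labels call the 4 replicates of each genotype independent, without saying whether each was an embryo, a litter or a pool, so the p-values measure the spread between these libraries. Each library was placed in its group by its genotype label.

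Reads were processed with Trimmomatic and STAR against mm10, per the submitters' processing notes; the versions and the gene models are not given in the sources used here. The deposited values are raw read counts per gene from STAR, not normalized, with an unstranded column and a column for each strand. Of the counts in the stranded columns, 98.1 to 98.5% lay in the column for the reverse strand in every library. That column was therefore used, by a rule set before the data were examined (over 80% in every library). The 4 summary rows of each table, which name no gene, were left out of library sizes and tests. They held 34.5 to 41.9% of the reads as assigned to no feature, 6.23 to 9.03% as multimapping, 7.77 to 12.1% as unmapped and 0.356 to 0.464% as ambiguous. Between 42.5 and 49.7% of reads were assigned to genes. STAR counts a read only where it maps uniquely and overlaps a single gene, so genes with near-identical copies are undercounted.

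The tables hold 24411 gene symbols, of which 24290 (99.5%) matched a RefSeq table of GRCm38.p6, the assembly behind mm10; positions are from that table, and the Atoh7 gene model is also given from GENCODE M21.

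Gene counts per library ranged from 19909452 to 25421526. Counts were filtered with filterByExpr, which left 14333 genes, scaled by TMM, and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust, in R 4.3.3) for KO against WT over all 8 libraries with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and every adjusted p of a single gene comes from this test unless another is named. Fold changes are log2 of KO over WT, the standard error (SE) is the absolute log2 fold change divided by the square root of F, and levels are TMM-scaled CPM values, counts relative to the library's scaled total, with the SD over 4 libraries. For a gene with 0 counts in all KO libraries the fold is a bound against a floor of 3 counts over the KO group; for a gene with 1 to 3 counts the ratio of summed counts is given with an exact 95% interval. These bounds and intervals use counts summed over the libraries of a group, so they leave out the spread between libraries. The reads carry no molecular identifiers, so repeated copies of a molecule may also be counted.

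Before the data were examined, 21 gene lists were fixed: RGC (retinal ganglion cell) transcription factors, RGC neuronal and cytoskeletal genes, axon guidance and adhesion, Hedgehog ligand and response, photoreceptor precursor, amacrine, horizontal cell, retinal progenitor, neurogenic progenitor, cell cycle, p53 targets and apoptosis, immediate early and stress, lens, pigment epithelium, endothelial, erythroid, macrophage and microglia, periocular mesenchyme, ciliary margin and optic stalk, skeletal muscle, and the chromosomal neighbours of Atoh7. Each was tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, two-sided, adjusted over the 21 lists). Alternatives were an estimated correlation and fry. The lists overlap in places; Neurod1, Otx2 and Hes6, for example, are in both the photoreceptor precursor and the neurogenic progenitor lists.

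The genes named were set by a rule fixed before the data were examined. It takes Atoh7; the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups; the 4 members of each list with the smallest p, and any member where the text counts members; all measured neighbours of Atoh7; Shh, Pou4f2, Isl1, Neurog2, Ascl1, Otx2, Crx, Ptf1a, Onecut1, Gli1 and Vsx2; and the sex-linked genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. Genes outside it are said to be chosen after their values were seen.

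The alternatives fixed beforehand were RLE and upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in 4 libraries, the unstranded column, the replicate number as a block, leaving out sex-linked genes, leaving out each library in turn, a fold threshold, DESeq2 1.42.0 and limma-voom. After seeing the data, fits were added without the library of each group highest in muscle, mesenchyme and endothelial markers, without both libraries with female expression of sex-linked genes, and with the mean of those non-retinal markers as a covariate. The calculation was tested on simulated counts of 14230 genes drawn from the means and depths of these libraries. In them 200 genes were changed by 1.5 to 8 times and a list of 25 more was raised 1.5-fold, all with a mean of at least 1 CPM. Of the 200 the calculation recovered 70% of those changed 1.5-fold, 74% at 2-fold, 98% at 4-fold and 96% at 8-fold (50 genes each), and of the 25 it recovered 11. Of its 195 calls, 15 (7.69%) were false. Replicates of a genotype differed by more than sampling noise in every pair, with chi-square per degree of freedom from 13.4 to 100.2, so none was counted as a repeat of another.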

Results

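Gene expression was profiled in retinae of E14.5 mouse embryos, the stage at which retinal ganglion cells (RGCs), the projection neurons of the eye, are being born. WT retinae were set against retinae lacking a large enhancer of Atoh7, with 4 libraries of each genotype. Atoh7 encodes a basic helix-loop-helix transcription factor needed for RGC genesis, and the series title places the comparison in a study of RGC genesis and axon formation. The WT libraries held 19909452, 25421526, 20907786 and 23074320 gene counts for replicates 1 to 4, and the KO libraries 21254788, 21977717, 21587826 and 24375241.

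Atoh7 itself was nearly undetectable in every KO library. Its level fell from 165 ± 11.1 CPM in WT to 0.498 ± 0.173 CPM in KO (SD, n = 4 each), a log2 fold change of -8.36 (SE 0.15, adjusted p = 6.48e-15) that left 0.302% of the WT level. The raw counts were 2784, 4292, 3862 and 3991 in the WT libraries and 8, 16, 12 and 8 in the KO libraries, so each library matched its genotype label. The gene lies on chromosome 10, from 63099785 to 63101280 in RefSeq on GRCm38, and GENCODE M21 places it on the plus strand with 2 transcripts. The labels describe the deletion as one of an enhancer, so the counts read the transcript and not the deleted DNA.

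Beyond Atoh7, the retinal transcriptome shifted broadly, with 1130 genes higher and 2144 genes lower in KO at an adjusted p below 0.05. Among these, 128 rose and 1004 fell by more than 1 on the log2 scale. Of the 14333 genes tested, 3719 had no overlap between KO and WT libraries, where chance gives 2.86% of genes. Chrnb3, a nicotinic acetylcholine receptor subunit, went from 7.08 ± 0.873 CPM in WT to 0 counts in all KO libraries, at least 212-fold lower. Shh, the secreted Hedgehog ligand made by RGCs, fell from 663 summed counts to 1, a ratio of 651 (95% interval 116 to 25749; at least 163-fold without KO replicate 2, which held that count), and the RGC transcription factor gene Pou4f3 from 418 to 3, a ratio of 137 (46.5 to 666). The next largest falls were in Mstn (log2 fold change -6.33, SE 0.26), Rph3a (-5.99, SE 0.20), a synaptic vesicle protein gene, Ecel1 (-5.90, SE 0.31, and -6.50 without KO replicate 1), the homeobox gene Nkx6-2 (-5.89, SE 0.46), Car10 (-5.76, SE 0.22), Tmem130 (-5.72, SE 0.17) and Cacng5 (-5.70, SE 0.23). C230091D08Rik also had 0 KO counts (at least 147-fold lower), but in the unstranded column its log2 fold change was -0.15 (adjusted p = 0.509), so its value depends on which strand the reads are given to.

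The genes that rose most were the homeobox genes Uncx (0.179 ± 0.112 to 4.72 ± 1.75 CPM, log2 fold change 4.68, SE 0.43) and En2 (3.67, SE 0.40). They were followed by Rgs13 (2.91, SE 0.28), Lrrc66 (2.26, SE 0.22) and Gpr34 (2.17, SE 0.30). Among more abundant transcripts, Sfrp2, which encodes a secreted modulator of Wnt signalling, rose from 372 ± 65.3 to 1415 ± 114 CPM (3.80-fold, SE 0.12 on the log2 scale). Bche rose from 23.9 ± 1.78 to 95.8 ± 15.7 CPM, and Crhbp rose by 1.94 on the log2 scale (SE 0.17). The remaining 4 of the 12 largest rises were in 6330403A02Rik (log2 fold change 1.97, SE 0.15), Trpc4 (1.84, SE 0.26), March11 (1.81, SE 0.13) and Sall4 (1.77, SE 0.19).

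**Figure D1:**
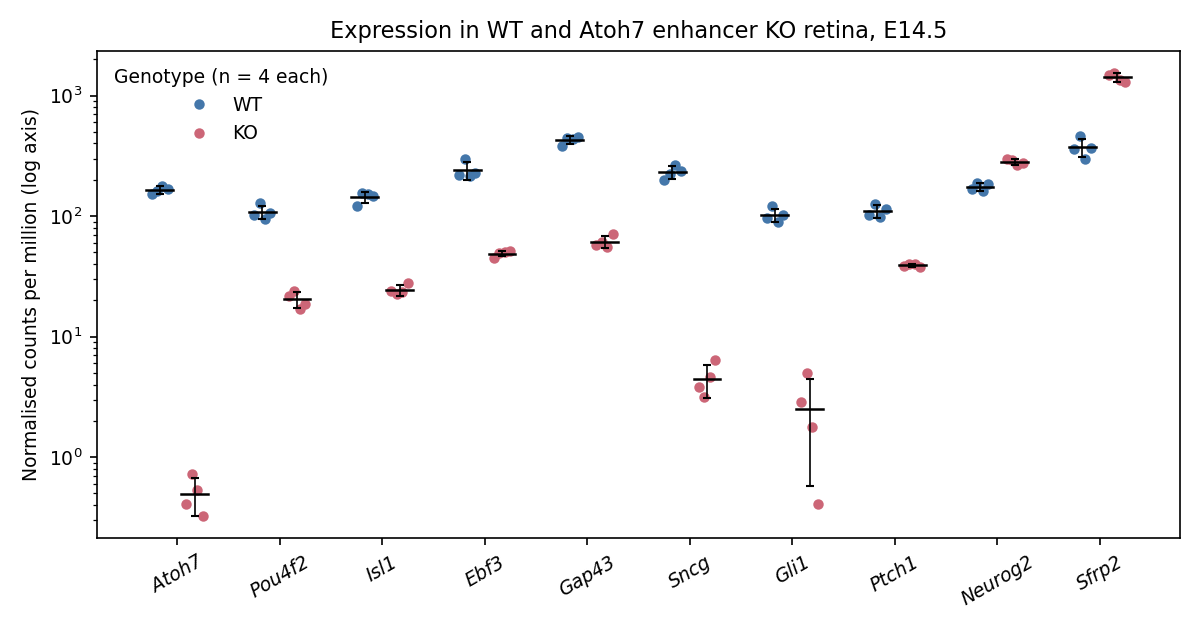
Normalised counts (CPM, log axis) of 10 genes in each WT and KO library; points are libraries, lines are means and bars are SD (n = 4 each). Atoh7 stood at 165 CPM in WT and 0.498 CPM in KO, while Neurog2 and Sfrp2 were higher in KO.

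Nearly all RGC neuronal and cytoskeletal genes were lower in KO. Of 32 measured, 31 fell and 0 rose by edgeR, also when adjusted over the list alone and at an unadjusted p below 0.05 (0 rose by DESeq2 or limma-voom), and the remaining member, Hpca, had a log2 fold change of -0.32 (adjusted p = 0.172). Islr2 fell from 456 ± 72.0 to 20.7 ± 2.72 CPM (log2 fold change -4.46, SE 0.13). Gal, a neuropeptide gene, fell by 4.54 on the log2 scale (SE 0.16), the neurofilament gene Nefl by 2.77 (SE 0.09), the growth cone gene Gap43 by 2.80 (SE 0.10) and the microtubule-associated protein gene Mapt by 4.46 (SE 0.16). The median log2 fold change of the list was -2.29, and the same with Chrnb3 at its bound (camera adjusted p = 1.77e-124). The call held with an estimated correlation (adjusted p = 0.00106).

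Of 28 RGC transcription factor genes, 21 fell and 0 rose by edgeR, also when adjusted over the list alone, at an unadjusted p below 0.05, and by DESeq2 and limma-voom. Pou4f2, a POU-domain factor that drives RGC differentiation, fell from 108 ± 14.1 to 20.4 ± 3.16 CPM (log2 fold change -2.41, SE 0.12). Its partner Isl1 fell by 2.56 on the log2 scale (SE 0.10), Pou4f1 by 2.34 (SE 0.11), Ebf3 by 2.29 (SE 0.11) and Myt1l by 4.88 (SE 0.19). Members that did not pass included Satb1 (log2 fold change 0.07), Lmo4 (0.18) and Tbr1 (0.08). The median was -1.76 (camera adjusted p = 1.22e-35, and adjusted p = 0.00870 with an estimated correlation).

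Axon guidance and adhesion genes mostly fell: of 33 measured, 20 fell, 5 rose and 8 did not pass, and adjusted over the list alone 22 fell and 5 rose. Igfbpl1 fell by 1.81 on the log2 scale (SE 0.10), the semaphorin receptor gene Nrp1 by 1.69 (SE 0.10), Dscam by 1.94 (SE 0.12) and Nfasc by 2.01 (SE 0.13). The 5 members that rose were Robo3 (log2 fold change 1.64), Boc (0.86), Zic2 (0.66), Epha4 (0.61) and Slit2 (0.52). The list median was -0.62 (camera adjusted p = 4.56e-09, and adjusted p = 0.230 with an estimated correlation).

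Among 10 Hedgehog ligand and response genes, 5 fell and 3 rose, also when adjusted over the list alone. Besides Shh, the falls were in 4 genes known as transcriptional targets of Hedgehog signalling. Gli1 fell from 102 ± 13.2 to 2.51 ± 1.93 CPM (log2 fold change -5.37, SE 0.56, adjusted p = 0.000610), and the log2 fold changes of Ptch2, Hhip and Ptch1 were -4.31 (SE 0.28), -3.55 (SE 0.17) and -1.49 (SE 0.09). Without KO replicate 2 the log2 fold change of Gli1 was -5.97. The genes that rose were Cdon (log2 fold change 0.97), a co-receptor gene, Gli3 (0.41) and Smo (0.38), the signal transducer gene. Gli2 (0.11) and Gas1 (-0.10) did not pass. The list median was -0.80, also with Shh at its ratio of counts (camera adjusted p = 1.65e-05, and adjusted p = 0.230 with an estimated correlation).

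**Figure D2:**
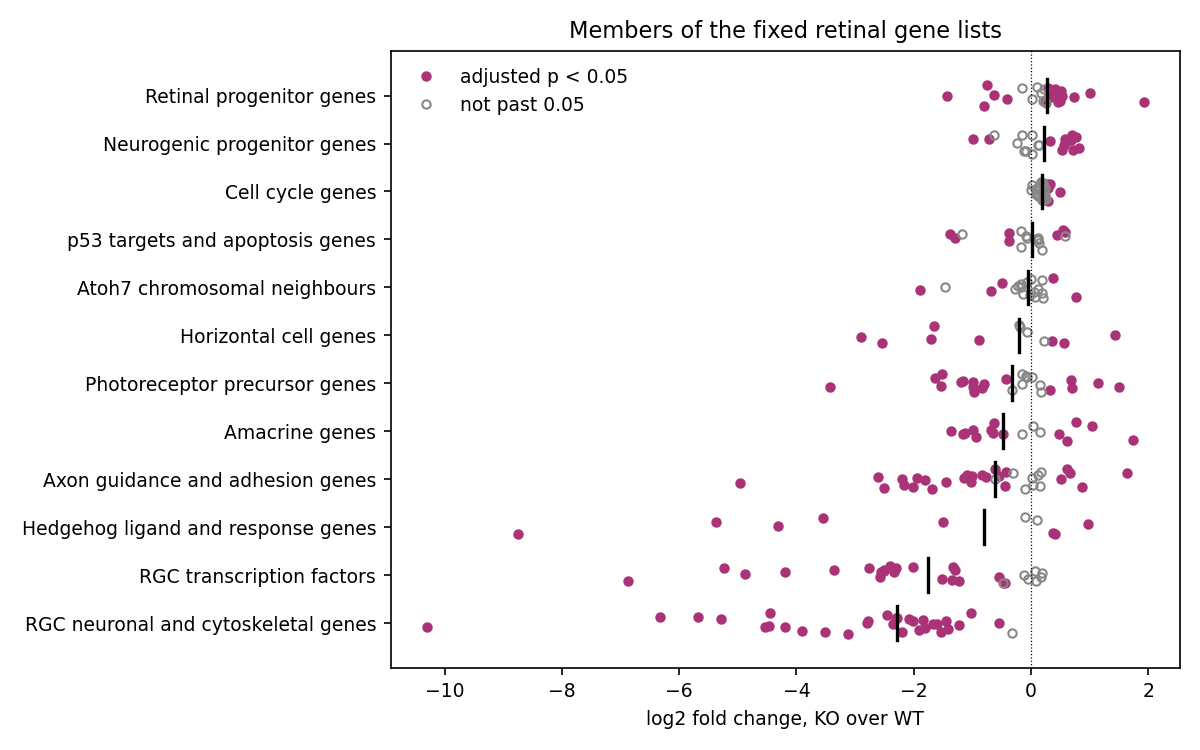
log2 fold change (KO over WT) of each measured member of the fixed retinal lists; filled points passed an adjusted p of 0.05, open points did not, and vertical lines are list medians. The RGC neuronal list lies furthest to the left, with a median of -2.29, and the retinal progenitor list furthest to the right, with a median of 0.27.

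Photoreceptor precursor genes went both ways: 12 of 25 measured fell and 5 rose, also when adjusted over the list alone. Rxrg, a cone nuclear receptor gene, fell by 1.63 on the log2 scale (SE 0.12), Gnb3 by 1.19 (SE 0.13), the cone channel gene Cngb3 by 0.97 (SE 0.11) and the short-wave opsin gene Opn1sw by 3.42 (SE 0.66). Impg2 had a log2 fold change of -1.51 (SE 0.12). Mesp2 (2.82-fold), Mybl1 (log2 fold change 1.14), Neurod1 (0.70), Samd11 (0.69) and Hes6 (0.33) rose. The early regulators of photoreceptor fate did not pass, with Otx2 at -0.09 (SE 0.08, adjusted p = 0.488) and Crx at -0.16 (SE 0.08, adjusted p = 0.158). The list median was -0.32, with a camera adjusted p of 0.0483 and an adjusted p = 0.635 with an estimated correlation. The list's call was lost without WT replicate 3 (adjusted p = 0.103) or 4 (0.0772), without KO replicate 1 (0.0864) or 3 (0.0749), in the unstranded column (0.0622), with the filter of at least 1 CPM in 4 libraries (0.0506), without both female libraries (0.0671) and with the non-retinal covariate (0.0694). With that covariate, or without KO replicate 4, 12 members fell and 3 rose.

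Amacrine and horizontal cell genes were also split. Of 17 amacrine genes, 5 rose and 9 fell, also when adjusted over the list alone. Bhlhe22 rose from 17.1 ± 3.19 to 57.6 ± 9.34 CPM (log2 fold change 1.75, SE 0.15), and Tfap2c (1.04), Lhx9 (0.77), Foxn4 (0.62) and Slc6a9 (0.48) rose as well. Tfap2a fell by 1.36 on the log2 scale (SE 0.13), the GABA transporter gene Slc6a1 by 1.16 (SE 0.13), Barhl2 by 0.99 (SE 0.13) and Ptf1a, needed for amacrine and horizontal fates, by 0.64 (SE 0.11). The list median was -0.47 and the list did not pass (camera adjusted p = 0.527). Of 12 horizontal cell genes, 3 rose and 5 fell, and adjusted over the list alone 4 rose and 6 fell. Esrrb fell by 2.89 (SE 0.39), Megf11 by 2.53 (SE 0.34), Ntrk1 by 1.65 (SE 0.28), Lhx1 by 1.70 (SE 0.31) and Onecut3 by 0.89 (SE 0.16), while Calb1 (log2 fold change 1.44), Onecut2 (0.57) and Onecut1 (0.35, SE 0.12, adjusted p = 0.0403) rose. The list median was -0.20 (camera adjusted p = 0.381). By fry, which does not compare the members with all other genes as camera does, the adjusted p was 0.0161. The call on Onecut1 was lost without WT replicate 1, 3 or 4 or KO replicate 3 or 4 (adjusted p from 0.0608 to 0.135), without the libraries highest in non-retinal markers (0.0579), without both female libraries (0.223) and with the non-retinal covariate (0.227), and without WT replicate 3 or KO replicate 3 only 1 member of the list rose and 5 fell.

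Most progenitor genes that changed were higher in KO. Levels are relative to the library's total, so a smaller share of RGCs would also raise progenitor and cell cycle genes. That was not tested apart from a rise within progenitors. Of 26 retinal progenitor genes, 14 rose and 5 fell, with 15 and 5 when adjusted over the list alone and 9 and 5 with the non-retinal covariate. Sfrp2 led the rises, followed by Lin28b (log2 fold change 1.01, SE 0.12) and the Notch effector gene Hes5 (0.73), and Vsx2, which encodes a homeodomain factor of retinal progenitors, rose from 411 ± 38.3 to 522 ± 34.6 CPM (0.35, SE 0.10). The falls were in Sox8 (-1.43, SE 0.12), Ccnd1 (-0.80, SE 0.10), Dapl1 (-0.76), Sox9 (-0.63) and Six3 (-0.41). Ccnd1, the main D-type cyclin of the retina and a very abundant transcript, went from 2974 ± 267 to 1703 ± 34.4 CPM. The call on Vsx2 was lost without KO replicate 4 (adjusted p = 0.0514) and with the non-retinal covariate (0.0735).

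Of 22 neurogenic progenitor genes, 11 rose and 2 fell, with 11 and 3 when adjusted over the list alone. Neurog2, a proneural factor gene, rose from 175 ± 13.6 to 282 ± 15.2 CPM (log2 fold change 0.69, SE 0.08), Btg2 rose by 0.83 (SE 0.08) and the Notch ligand gene Dll1 by 0.76 (SE 0.09). The other proneural factor of the list, Ascl1, fell from 150 ± 18.7 to 91.1 ± 4.68 CPM (-0.72, SE 0.09), and Elavl2 fell by 0.99 on the log2 scale (SE 0.10). Of 28 cell cycle genes, 6 rose and 0 fell by edgeR, also when adjusted over the list alone, with 12 and 0 at an unadjusted p below 0.05, 9 and 0 by DESeq2 and 5 and 0 by limma-voom. They were Ccne1 (log2 fold change 0.50, SE 0.12), Aurka (0.33, SE 0.08), Ccne2 (0.30, SE 0.09), E2f1 (0.29, SE 0.09), Rrm2 (0.28) and Tyms (0.23). Without single libraries the call on E2f1 was lost for 6 of the 8 libraries (all but WT replicates 2 and 4, adjusted p from 0.0541 to 0.133) and that on Ccne2 for WT replicate 2 (0.0708) and KO replicate 1 (0.0800). E2f1 was also lost without the libraries highest in non-retinal markers (0.0785), without both female libraries (0.0917) and with the non-retinal covariate (0.290), and Ccne2 in the unstranded column (0.141). Without KO replicate 1 or KO replicate 4, 3 cell cycle genes rose.

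The medians of these lists were 0.27 for retinal progenitors, 0.23 for neurogenic progenitors and 0.19 for the cell cycle. Their camera adjusted p-values were 0.00785, 0.00785 and 0.00581. With an estimated correlation, the adjusted p = 0.635 for both progenitor lists and adjusted p = 0.235 for the cell cycle list. A p as small was reached in 11, 8 and 12 of the 35 splits of the 8 libraries, the real split included. Splits that divide a genotype unequally keep part of the genotype difference, so these counts do not measure chance alone.

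Genes of cell death and stress showed no common direction. Of 18 p53 target and apoptosis genes, 3 rose and 4 fell, also when adjusted over the list alone. Bcl2l11 (log2 fold change 0.45, SE 0.09), Sesn2 (0.55, SE 0.14) and Eda2r (0.59) rose, and the cell cycle inhibitor gene Cdkn1a (-1.39, SE 0.28), Hrk (-1.30, SE 0.28), Bbc3 (-0.38) and Trp53inp1 (-0.37) fell. The list's median was 0.02 and its mean -0.12, opposite in sign, and camera did not call it (adjusted p = 0.756). Of 17 immediate early and stress genes, which respond to handling of tissue, Jun rose (0.51, SE 0.10) and Klf6 fell (-0.38, SE 0.08), also when adjusted over the list alone, with a list median of 0.06 (camera adjusted p = 0.534). In this list 2 genes rose without WT replicate 1 or KO replicate 3, without the libraries highest in non-retinal markers, without both female libraries and with the non-retinal covariate.

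Genes around Atoh7 on chromosome 10 changed by far less than Atoh7 itself. Within 1 Mb on each side, 6 of 25 other genes tested passed, of which 2 rose and 4 fell. Among all 14333 genes tested, 1130 were higher and 2144 lower, so the region did not stand out by its share of changed genes. Of 20 measured members of the neighbour list, 2 rose and 3 fell, also when adjusted over the list alone. Those that rose were Dnajc12, 281 kb away (log2 fold change 0.76, SE 0.13), and Dna2 (0.37, SE 0.09), and those that fell were Hk1 (-0.67, SE 0.13), Hkdc1 (-0.49, SE 0.12) and Lrrtm3 (-1.88, SE 0.42, and -2.48 without KO replicate 3). The flanking genes did not pass: Mypn, the nearest tested gene, had a log2 fold change of -1.47 (SE 0.83, adjusted p = 0.264), Pbld2 -0.22 (SE 0.39), Hnrnph3 -0.14 (SE 0.11), Rufy2 -0.07 (SE 0.11), Herc4 -0.02 (SE 0.09) and Sirt1 -0.00 (SE 0.11). Mypn was past the threshold only when WT replicate 2 was left out (-1.84, adjusted p = 0.0324), among the alternatives run, and Hnrnph3 only when both female libraries were left out (-0.30, adjusted p = 0.0209). With no low-count filter 5 members of 24 fell. The list median was -0.05 (camera adjusted p = 0.756).

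**Figure D3:**
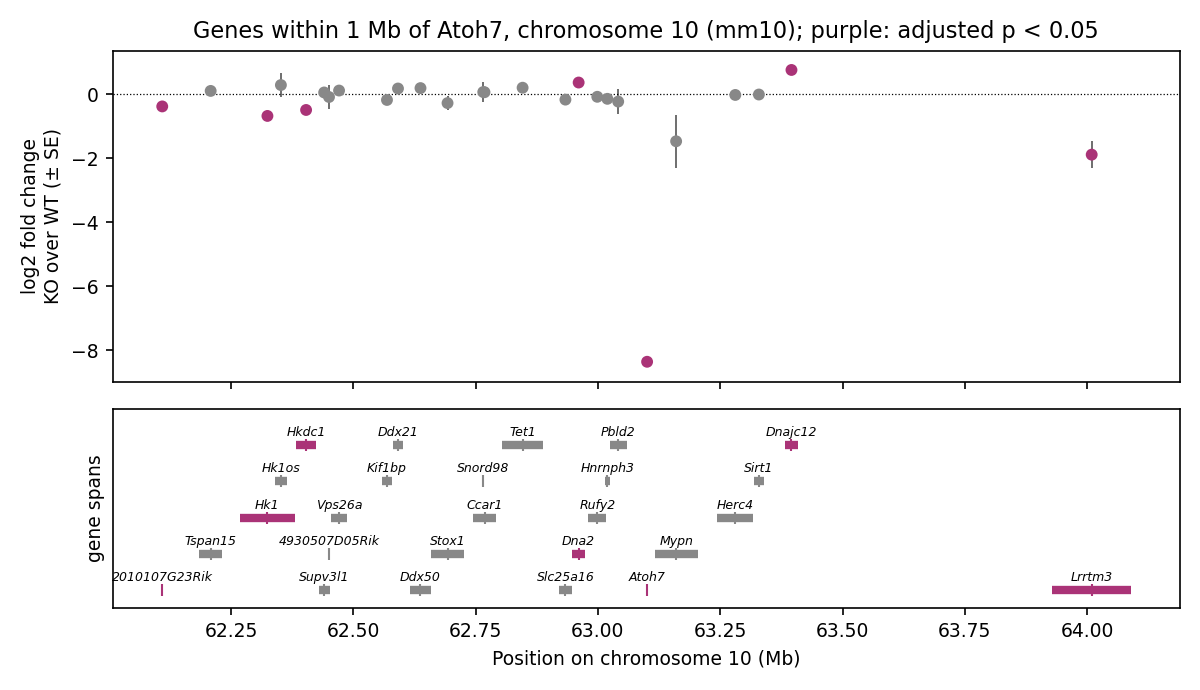
log2 fold change (KO over WT, bars ± SE, n = 4 each) of genes within 1 Mb of Atoh7 against their position in Mb on chromosome 10, with gene spans below; purple marks an adjusted p below 0.05. Atoh7, at -8.36, stands apart from its neighbours, of which Dnajc12 (0.76) and Lrrtm3 (-1.88) are the extremes among those past the threshold.

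Macrophage and microglia genes were higher in KO. Of 17 measured, 9 rose and 0 fell by edgeR, with 11 and 0 when adjusted over the list alone or at an unadjusted p below 0.05 and 9 and 0 by DESeq2 and limma-voom, and the median log2 fold change was 0.72. Cx3cr1, a microglial chemokine receptor gene, rose from 3.96 ± 1.05 to 9.62 ± 0.758 CPM (1.29, SE 0.17), P2ry12 rose by 1.14 (SE 0.19) and the complement gene C1qb by 0.72 (SE 0.15) on the log2 scale. Its partner gene C1qc rose from 4.68 to 9.32 CPM (SE 0.17 on the log2 scale). The camera adjusted p was 0.000658, with an adjusted p = 0.635 with an estimated correlation, and 11 of the 35 splits of the libraries gave a p as small. That count does not measure chance alone, because splits that divide a genotype unequally keep part of the genotype difference. Without WT replicate 2, 7 members rose and 1 fell.

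Markers of tissue around the retina varied widely between libraries of both genotypes. The mean over lens genes ranged from 1.502 to 6.503 log2 CPM in WT and from 0.563 to 6.002 in KO, and that over skeletal muscle genes from 1.13 to 4.16 and from 0.64 to 2.84. No member passed among 20 lens genes (median log2 fold change -0.90, camera adjusted p = 0.562), 13 muscle genes (-1.47, 0.293), 18 periocular mesenchyme genes (-0.74, 0.562), 15 pigment epithelium genes (0.05, 0.823) or 7 erythroid genes (1.03, 0.293), by edgeR or when adjusted over the list alone. At an unadjusted p below 0.05 these lists had 0, 1, 3, 3 and 2 members, by DESeq2 0, 2, 3, 1 and 3, and by limma-voom 0, 0, 0, 2 and 0. The erythroid members called by DESeq2 were the embryonic globin genes Hbb-y, Hba-x and Hbb-bh1, higher in KO. Of 15 endothelial genes, only Flt1 fell (-1.99, SE 0.48; list median -0.91, adjusted p = 0.526), and it alone passed when adjusted over the list alone. Of 12 ciliary margin and optic stalk genes, Wfdc1 (1.70, SE 0.47, adjusted p = 0.0378) and Otx1 (1.02, SE 0.21) rose and Pax2 (-1.74, SE 0.26), an optic stalk gene, fell, also when adjusted over the list alone (median 0.10, adjusted p = 0.527). The lens list passed without KO replicate 1 (adjusted p = 0.00461) and the muscle list without WT replicate 2 (0.00708) or KO replicate 2 (0.0145) or without the libraries highest in non-retinal markers (0.0260), each with lower values in KO. The call on Wfdc1 was lost without WT replicate 1, 2 or 3 or KO replicate 1, 3 or 4 (0.0719 to 0.0899), with a log2 fold change of 2.35 without WT replicate 4. That call was also lost with no low-count filter (0.0643), without the libraries highest in non-retinal markers (0.0872), without both female libraries (0.105) and with the non-retinal covariate (0.177), and that on Flt1 without both female libraries (0.0544). With the non-retinal covariate the median log2 fold changes of the lens, endothelial and mesenchyme lists were 0.52, 0.04 and 0.05. That covariate is the mean of the muscle, mesenchyme and endothelial lists. Values near 0 for the mesenchyme and endothelial lists therefore follow partly from its construction, and their counts under it are not independent results. The lens median was 0.34 without WT replicate 3, -4.27 without KO replicate 1 and -2.03 with the replicate block. The erythroid median was 0.16 without KO replicate 2 and 1.93 without WT replicate 1. With the non-retinal covariate 6 erythroid and 4 pigment epithelium genes rose, 7 mesenchyme genes rose and 3 fell, and 1 endothelial gene rose and 1 fell. Without the libraries highest in non-retinal markers 3 muscle genes and 1 pigment epithelium gene fell, and 1 mesenchyme gene rose and 1 fell. Without WT replicate 2, 4 endothelial and 2 muscle genes fell and 1 endothelial gene rose, and without KO replicate 2, 2 endothelial, 2 muscle, 1 mesenchyme and 1 pigment epithelium gene fell. Single members also passed without WT replicate 1 or without both female libraries (1 mesenchyme gene rose), without WT replicate 4 or with at least 1 CPM in 4 libraries (1 pigment epithelium gene fell), without KO replicate 1 (1 lens gene fell) and without KO replicate 3 (1 muscle gene fell); 2 erythroid genes rose without KO replicate 4, and 2 endothelial genes fell in the unstranded column.

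**Figure D4:**
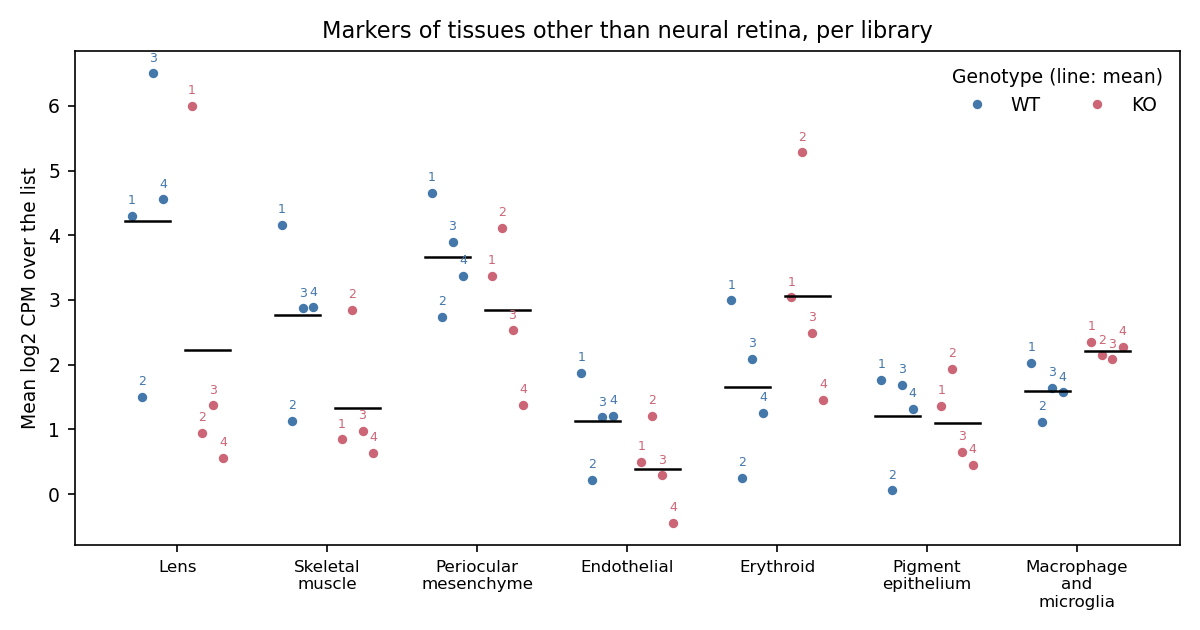
Mean log2 CPM over lists of marker genes for tissues other than neural retina, for each library (digits are replicate numbers, lines are group means). Lens means reached 6.503 in WT replicate 3 and 6.002 in KO replicate 1, and macrophage means were higher in every KO than in every WT library.

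The genotype separated the libraries on the main axis of variation (60.3% of variance). The next axis (15.3%) had WT replicate 1 and KO replicate 2 at its high end, the libraries of each group with the highest means over muscle, mesenchyme and endothelial markers. Without both, 1167 genes were higher and 2132 lower in KO. WT replicate 1 and KO replicate 3 had female expression of sex-linked genes, with Xist at 1983 and 4049 CPM against at most 1.27 CPM in the other libraries; without both, 1391 genes were higher and 2171 lower. The genes Ddx3y, Eif2s3y, Kdm5d and Uty stood at 1.03 to 2.50 CPM in WT replicate 1 and 0 to 0.177 CPM in KO replicate 3, against 38.3 to 72.9 CPM in the others.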

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

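The counts of other splits of the libraries and the test of early-stage growth genes were set before their results were seen; all other tests in this part were chosen afterwards. None of the 34 other splits of the 8 libraries into 4 and 4 came near the number of genes changed between KO and WT. Only 1 of the 35 splits, the real one, gave 3274 genes, and the highest of the others gave 11. A share of 1 in 35, the smallest these splits can give, argues against chance without excluding it. In every other split the genotype difference also lies within the groups, so their counts are not those of libraries without such a difference. For the number of gene lists past camera's threshold, the splits do not exclude chance. Of the 35, 16 gave 9 or more lists, up to 13. They cannot measure chance alone either, because splits that divide a genotype unequally keep part of the genotype difference. Of the 15 others with 9 or more lists, 12 called the RGC transcription factor list and 11 the lens list. The count depends on the preset correlation: with an estimated correlation the real split gave 2 lists and no other split more than 1. The real split had the smallest p of all 35 for the RGC transcription factor, RGC neuronal, axon guidance and Hedgehog lists.

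RGC genes fell by unequal factors. Low counts as the source of the spread are argued against by the 29 RGC list members with a WT mean of at least 50 CPM, whose log2 fold changes spanned 5.756, from Sncg (-5.69) to Satb1 (0.07), although members such as Satb1 are also expressed outside RGCs. Loss of a fixed share of otherwise like RGCs would lower genes known as restricted to RGCs alike. Among those with more than 3 KO counts, the log2 fold changes were -1.51 for Isl2, -1.53 for Rbpms, -2.34 for Pou4f1 and -2.41 for Pou4f2. Sncg alone, at -5.69, widened the range to 4.176. Pou4f3, with 3 KO counts, was left out of that range and stood at -6.87 (SE 0.39). Loss of a fixed share cannot be told apart from unequal regulation. The reason is that these genes were picked after their values were seen and bulk counts do not show how much other cells express them. A difference in age or state of the RGC-like cells left in KO also stays open, untested.

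The mean over macrophage and microglia genes was higher in every KO than in every WT library, although only 9 of 17 members passed (not Mrc1 at -1.05, Spi1 at 0.02 or Lyz2 at 0.08, among others) and the list's call was lost with an estimated correlation (adjusted p = 0.635). More vessel tissue carried over in KO is argued against, because the macrophage mean less the endothelial mean was 1.359 log2 units higher in KO. Every KO library lay above every WT library (exact permutation p = 0.0286, two-sided, the smallest this test can give). Much of that difference came from the endothelial mean, with a KO minus WT value of -0.733 (exact permutation p = 0.286). The macrophage mean alone was 0.626 higher in KO. More blood as the whole cause is argued against less strongly: the mean of Slc4a1, Alas2, Gypa and Klf1 was 0.315 log2 units higher in KO (exact permutation p = 0.743), and with it as a covariate in a linear model the macrophage mean was 0.5905 higher in KO (95% interval 0.123 to 1.06), against 0.626 without it. A smaller share of RGCs, which raises every other cell type alike, cannot be told apart from a rise in macrophages, because the macrophage mean less the cell cycle mean was 0.4376 higher in KO with overlapping libraries (exact permutation p = 0.0571). More microglia, or microglia in another state, may follow the loss of RGCs; that stays a hypothesis without a test here.

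Embryonic globin transcripts were higher in KO relative to other red cell genes. The ratio of Hbb-y to the sum of Slc4a1 and Alas2 was 0.277 to 0.448 in the WT libraries and 3.62 to 5.31 in the KO libraries, a log2 difference of 3.576 (11.9-fold, exact permutation p = 0.0286, two-sided), which more blood in the KO libraries would not give. A sequence variant at a single globin locus is argued against by Hba-x, on another chromosome, whose ratio was 2.749 log2 units higher (6.72-fold, exact permutation p = 0.0286). KO embryos at an earlier stage, when more red cells carry embryonic globins, stay a candidate explanation. Of 9 growth genes known to decline with age, 5 rose and 0 fell, and Hmga1 (-0.22), Arid3a (-0.20) and Nr6a1 (-0.01) had negative values without passing. As a set these growth genes met the bound set beforehand, with a median log2 fold change of 0.2654 and a directional fry rotation p of 0.00454. A genotype effect also stays open, because retinal progenitors express these genes, the progenitor list's median was 0.27, and the difference between the means of both sets, a comparison added after the result was seen, was 0.140 log2 units higher in KO (exact permutation p = 0.0857); litter and strain background, which the labels do not give, were untested.

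In 302 groups of 4 libraries examined, 22 had a library far from the other 3, where chance gives about 15.1 (1 in 20). All values here are log2 CPM. Shh stood at -2.892 and Pou4f3 at -3.484 in KO replicate 2, both near the floor, En2 at -2.973 and Islr2 at 9.138 in WT replicate 2, and Rgs13 at 1.299 and E2f1 at 6.166 in KO replicate 4. KO replicate 3 stood apart in Bcl2l11 (5.85), Onecut1 (5.804), Tet1 (6.939) and Ccar1 (7.769). Fosb (-1.703) and Hnrnph3 (5.465) stood apart in WT replicate 1, and Klf1 (-1.842) in WT replicate 2. KO replicate 1 stood far above the other KO libraries in the lens genes Bfsp1 (4.942) and Crygb (6.46) and in the lens list mean (6.002). KO replicate 2 was high in the muscle genes Mylpf (3.337) and Acta1 (4.187) and in the muscle list mean (2.843), and low in Rgr (-0.7663). The amacrine mean was low in KO replicate 3 (4.092) and the retinal progenitor mean in WT replicate 3 (7.418).

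The column of counts for the opposite strand, used in no comparison above, held 304960 to 440952 counts per library. In it, 72 of 4454 genes tested were higher and 184 lower in KO by the edgeR test, and 22 and 53 of these were called in the same direction on their own strand.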

How the results depend on the processing

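The fits without the libraries highest in non-retinal markers, without the female libraries and with a non-retinal covariate were chosen after seeing the data. Under every alternative run at an adjusted p of 0.05, the genes higher in KO numbered 795 to 1506 and those lower 1874 to 2298, within 1.5 times 1130 and 2144. Leaving out each library in turn gave 795 to 1461 higher and 1874 to 2166 lower, the lowest without WT replicate 4 and KO replicate 1. Upper-quartile scaling gave 1506 and 2035, DESeq2 1349 and 2298, limma-voom 1159 and 2148, the unstranded column 1103 and 2136, and the non-retinal covariate 948 and 1992. A log2 fold change beyond 1 left 128 and 1004, by construction. The log2 fold change of Atoh7 ranged from -8.63 to -8.18 over its alternatives. Gene lists past the threshold numbered 9 by camera, 10 by fry and 2 by camera with an estimated correlation. The preset correlation was 0.01, and the estimates ran from 0.0283 for the Atoh7 neighbours to 0.975 for lens genes. Other causes of the difference were not tested. Replicate numbers did not pair the libraries (correlations of same-numbered deviations from -0.34 to 0.22, and no same-numbered libraries were each other's best match), and the replicate block gave 1137 and 2116 genes and 8 lists; it ended the calls on the photoreceptor precursor list (adjusted p = 0.0989), Onecut1 (0.0556) and Cdkn1a (0.0608), and left 1 horizontal cell gene that rose, against 3. For single named genes, 2545 of 2660 alternative values kept their direction and side of the threshold, 36 passed newly (18 genes), 36 no longer passed (8 genes) and 43 turned sign (11 genes), all of these in genes that passed neither way. Sirt1 turned with RLE (0.00202) and upper-quartile scaling (0.0312), no low-count filter (0.00344), the unstranded column (0.00684) and DESeq2 (0.00341), and Herc4 with upper-quartile scaling (0.0159). With the non-retinal covariate Cryab (0.118), Crygb (0.0567), Pbld2 (0.0970), Ccar1 (-0.0104), Ddx3y (-0.0261) and Kdm5d (-0.0870) turned, without the female libraries Pbld2 (0.0643), Ccar1 (-0.105) and Xist (-0.220), without the libraries highest in non-retinal markers Ddx3y (-0.427), Kdm5d (-0.581) and Uty (-0.376), and by limma-voom Ddx3y (-0.910), Kdm5d (-1.51) and Uty (-1.56). Leaving out each library in turn gave -0.0836 to 0.0304 for Herc4, -0.0705 to 0.0715 for Sirt1, -0.0171 to 0.117 for Ccar1, -9.30 to 10.1 for Xist, -0.262 to 0.529 for Ddx3y, -0.678 to 0.126 for Eif2s3y, -0.352 to 0.455 for Kdm5d and -0.214 to 0.588 for Uty. Lists that passed neither way turned direction 12 times: the Atoh7 neighbours with no low-count filter (adjusted p = 0.928), without the female libraries (0.838) and by fry (0.5003), mesenchyme without the female libraries (0.838) and with the covariate (0.284), lens (0.850) and endothelial (0.620) genes with the covariate, p53 targets by fry (0.609), and pigment epithelium by fry (0.753) and without single libraries (0.606 to 0.926 over all). With the non-retinal covariate the erythroid list (adjusted p = 2.74e-09) and the pigment epithelium list (0.0125) passed. The mesenchyme and endothelial lists are part of that covariate, so their turns with it follow partly from its construction. In simulated counts at this depth 70% of 50 single genes changed 1.5-fold were recovered, and 11 of the 25 list genes raised 1.5-fold. Changes of that size or smaller can therefore be missed. Genes with few counts may be missed as well, which the simulation did not test, since it changed only genes with a mean of at least 1 CPM. It also changed far fewer genes than were called in the data, so the shares recovered need not hold for these libraries.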

Other observations

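The tests of gene families in this part were chosen after the results were seen, and the families were formed by shared symbol stems with at least 10 measured members (157 families). Those described are some of the families past camera's threshold, and none of the 157 passed with an estimated correlation. Of 10 measured voltage-gated sodium channel (Scn) genes 8 fell, with a median log2 fold change of -1.76 (camera adjusted p = 3.32e-10, but adjusted p = 0.360 with an estimated correlation). Scn3b fell from 54.6 ± 6.55 to 1.86 ± 0.503 CPM (log2 fold change -4.86, SE 0.16) and Scn9a from 56.8 ± 15.3 to 2.66 ± 1.13 CPM (-4.40, SE 0.35), while Scn8a stood at 0.12 and Scn11a at 0.35 without passing. Of 15 synaptotagmin genes, which encode calcium sensors of vesicle release, 8 fell, led by Syt4, Syt6 (-3.77, SE 0.30) and Syt13 (-3.12, SE 0.12), and Syt2 (1.10) and Syt9 (0.46) rose (camera adjusted p = 3.70e-11, but adjusted p = 0.318 with an estimated correlation). Scn3a, Syt4 and Syt13 are also in the RGC neuronal list.

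Of 21 measured clustered protocadherin genes of the beta group, which encode adhesion molecules of neurons, 16 fell and the others did not pass, with a median log2 fold change of -0.94 (camera adjusted p = 0.000837, but adjusted p = 0.904 with an estimated correlation). Pcdhb15 fell by 1.58 on the log2 scale (SE 0.28), and Pcdhb17 went from 11.2 ± 1.19 to 5.56 ± 1.07 CPM (SE 0.15 on the log2 scale); these genes are similar in sequence, so their unique reads are uncertain. Of 20 semaphorin genes, 12 fell, among them Sema6d (-2.15, SE 0.14), and Sema3g rose (1.69, SE 0.26); camera gave an adjusted p of 0.000185, but adjusted p = 0.904 with an estimated correlation. Of 47 Rpl genes, which encode ribosomal proteins and relatives, 6 rose and the others did not pass (median 0.24), and 10 rose with upper-quartile scaling (median 0.28); camera gave an adjusted p of 0.00320, and adjusted p = 0.936 with an estimated correlation. Of 46 genes with the symbol stem Rps, 5 rose and 2 fell (median 0.24, camera adjusted p = 0.0339, but adjusted p = 0.936 with an estimated correlation). With RLE 9 rose, and with upper-quartile scaling 10. A stem ends at the first digit or hyphen of a symbol, so this one can take in kinase genes beside ribosomal protein genes. Which kind rose or fell was not separated. The median of no family named here changed direction under RLE or upper-quartile scaling.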
